A study of Arabidopsis thaliana with 6 samples.

How the data were processed

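DNA methylation was measured by whole-genome bisulfite sequencing of rosette leaves of 5-week-old Arabidopsis thaliana Col-0 plants, with 3 libraries from plants sprayed with a water control at 2 weeks of age and 3 from plants sprayed with 1 mM JA, and Silwet L-77, a surfactant, was in both sprays at 0.02%. Per the labels, the libraries were sequenced as 150 bp paired-end reads, and the submitters' notes name Trimmomatic 0.38, Bismark 0.21.0 and Bowtie2 2.3.4.1 with the TAIR10 genome. The deposited values are counts, for each of 43080080 cytosines per library, of reads that called it methylated and reads that called it unmethylated, with its strand, context and trinucleotide. The notes do not state deduplication or filters, and reads are not independent molecules, so errors from counting alone would be too small; all errors given are between libraries. Depth per library stands at the start of the results.

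The counts were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and pyarrow 21.0.0, statistics were computed with scipy 1.17.1 and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and plots were drawn with matplotlib 3.10.9. The level of a library is methylated reads divided by all reads, over the 5 nuclear chromosomes and per context. It was compared between groups by a two-sided exact permutation test over the 10 splits of 3 against 3. Trinucleotides were tested in the same way, with Benjamini-Hochberg adjustment over the 12. Bins of 100 bp were classed by the level pooled over all 6 libraries. TE-like bins have CHG of at least 20% or CHH of at least 10%. Gene-body-like bins have CG of at least 20% with CHG and CHH under 5%. Unmethylated bins have all contexts under 5%, and the remaining bins form a class of their own.

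Features were 100-bp bins, bodies of 27444 protein-coding genes, their 1-kb flanks and 3917 pseudogene loci. Cytosines needed at least 4 reads in every library, and a feature needed at least 4 such cytosines and a pooled level of at least 5%. Summed counts were fitted per feature and context with a quasi-binomial logistic model. Dispersions were squeezed across features by limma's squeezeVar method, ported to Python and checked against limma, with a floor of 1. The deviance F test was two-sided, with Benjamini-Hochberg adjustment over all features of a kind tested in a context, and a call was an adjusted p under 0.05. The test was tried on simulated data of the same depth with 200 changed features of known size. All were changed at once, and each change raised a low level or lowered a high one. Many true changes make the adjusted threshold easier to pass, so the shares recovered can be too high for data with few changes. The simulated spread between libraries was 1 value per kind and context, set from the mean and the same at every depth. In very deep bins the test called too many unchanged simulated features. A dispersion prior that follows coverage (limma's trended squeezeVar on log mean reads) was therefore added as an alternative, while the planned test was kept.

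The groups, features, tests, gene lists and the settings varied in turn below were fixed before the data were examined. The same holds for the rule for named features: per context, among called bins without overlap of the groups the 5 with the largest change in each direction, and among called genes and flanks the 5 with the lowest p in each direction. Where nothing was called, the 5 with the lowest p are given as not passing, and from each of the 8 gene lists the 1 feature with the lowest p. Other features of the lists with a low p, and TPC1, were named after their values were seen. Settings tried in turn were coverage minimums of 8 and 1 reads, no level filter, edgeR's quasi-likelihood test, limma on arcsine square root levels, Fisher's exact test on pooled counts, the replicate number as a block, an offset at the library-wide level, a minimum difference of 40, 20 or 10 points in CG, CHG or CHH, bins of 200 bp, flanks of 500 bp, lower class limits of 10% CHG or 5% CHH, per-cytosine means, subtraction of the chloroplast level, and leaving out each library.

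Chosen after seeing the data were pseudogene loci as features, the prior that follows coverage, an offset at the mean of the tested features, removal of cytosines or features with more than 100 reads per cytosine and library (collapsed repeats), bins of 1000 bp, per-cytosine means at 4 reads, classes weighted by their number of cytosines, adjustment over all features of a gene list together, and all comparisons by 500-kb window and by cytosine level. For the classes and trinucleotides, leaving out single libraries, the replicate block and per-cytosine means were likewise chosen after seeing the data, as were, for the classes, the coverage minimum and the chloroplast correction.

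Genes came from a RefSeq gene table on TAIR10.1, which gives no strand and no transposable elements. Tests of single transposable elements, of their families and of the ATREP2 family were therefore not run. Flanks on both sides replaced the planned upstream promoters, and a bin between genes is named by the nearest gene edge. Coordinates of the table and the counts were checked against each other: CHG methylation inside genes was 1.49% with the table in place and rose to 3.83% and 3.92% when it was shifted by 5000 bp to either side. In the lists, FMOGS-OX1 is the gene the table calls FMO GS-OX1, and RPP7 was matched by its locus AT1G58602. The numbers of the replicates showed no strong pairing of the libraries: correlations of same-numbered replicates over features ran from -0.109 to 0.0756. All 3 were positive for CG gene bodies (0.0319 to 0.0756), CG flanks (0.0157 to 0.0441), CHH flanks (0.0129 to 0.0226) and CHH bins (0.0047 to 0.0138). In the other sets not all were positive. A weak pairing is thus not excluded. No batch is given in the labels.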

Results

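Whole-genome bisulfite sequencing was used to measure DNA methylation at single cytosines in rosette leaves of Arabidopsis thaliana ecotype Col-0. Plants had been sprayed once as seedlings, at 2 weeks of age, with 1 mM jasmonic acid (JA, a plant hormone of wound and herbivore defence) or with a water control holding the same share of ethanol, and leaves were taken at 5 weeks. There were 3 biological replicates of each treatment, and each library came from 12 leaves of 6 plants. The comparison of JA with water asks whether a seedling treatment left a mark in the methylome of leaves sampled 3 weeks afterwards. Methylation was taken in the sequence contexts CG, CHG and CHH, where H is A, C or T.

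The water libraries held 248902560, 269826578 and 277286611 cytosine calls for replicates 1, 2 and 3. The JA libraries held 240486838, 221216764 and 232152023. Mean depth per nuclear cytosine was 5.41, 5.93 and 6.13 reads in the water libraries and 5.20, 4.83 and 5.11 reads in the JA libraries, so every JA library was shallower than every water library. A depth of at least 4 reads in every library was reached by 1802637 CG cytosines (32.4%), 1919529 CHG cytosines (31.5%) and 6323879 CHH cytosines (20.3%). Chloroplast DNA took 6.00%, 4.91% and 4.56% of the calls in the water libraries and 6.36%, 5.52% and 4.94% in the JA libraries. The level at chloroplast CG cytosines, which carry no methylation and give the non-conversion background, was 0.381% ± 0.0482 (SD, n = 3) after water and 0.379% ± 0.0394 after JA.

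Leaves of water-treated and JA-treated plants had similar methylation over the nuclear genome as a whole. Methylated reads made up 32.5% ± 1.55 (SD, n = 3) of the reads on CG cytosines after water and 31.5% ± 1.37 after JA. In CHG the levels were 11.7% ± 0.838 and 10.8% ± 0.891. In CHH they were 3.57% ± 0.310 and 3.32% ± 0.317. The differences, JA minus water, were -0.976 percentage points in CG (SE 1.19), -0.927 in CHG (SE 0.706) and -0.249 in CHH (SE 0.256), with two-sided exact permutation p of 0.5, 0.3 and 0.4. These lay within the spread between replicates. With 3 libraries against 3 the smallest p such a test can give is 0.1, for these and all other levels per library below. The CG difference changed sign when each cytosine rather than each read counted once, to 28.1% ± 0.189 after water and 28.5% ± 0.113 after JA, a difference of 0.433 points with all 3 JA libraries above all 3 water libraries (exact permutation p = 0.1).

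**Figure D1:**
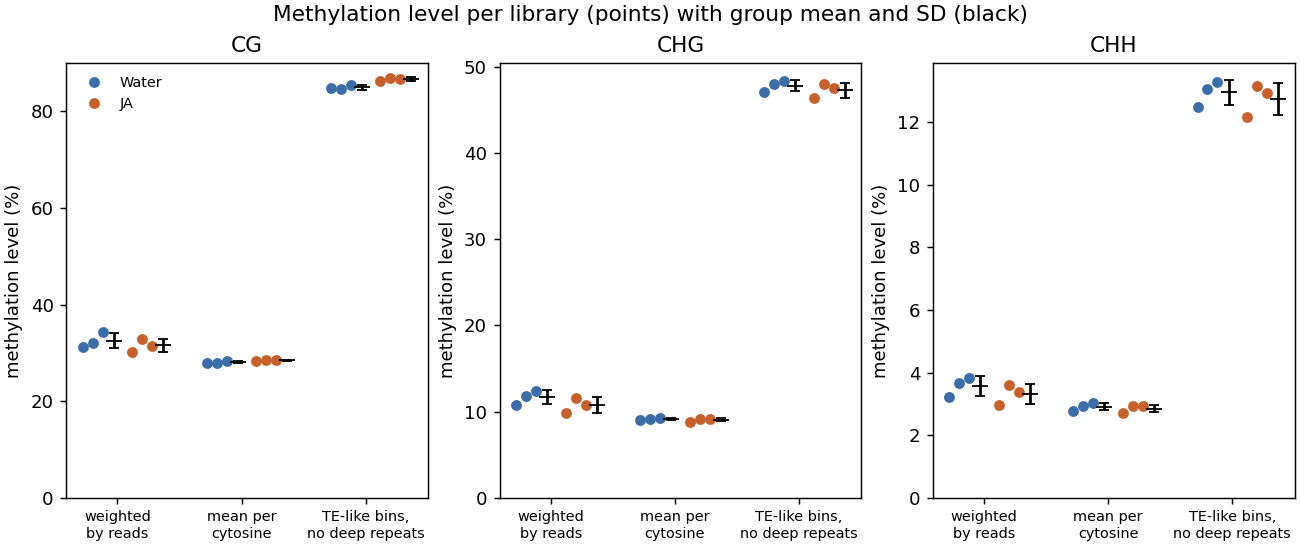
Methylation level in percent (vertical axis) of each library (points, blue for water and orange for JA), with the group mean and SD in black, for nuclear cytosines weighted by reads, for the mean per cytosine, and for TE-like bins without deeply read repeats, in CG, CHG and CHH. In TE-like bins the CG level had a mean of 85.0% after water and 86.7% after JA, with no overlap of the groups, while the groups overlapped in CHG and CHH.

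The trinucleotide context separates the enzymes that place methyl groups outside CG: CMT2 prefers CAA and CTA. At CAA and CTA the level was 7.50% ± 0.615 (SD, n = 3) after water and 6.96% ± 0.701 after JA. The other CHH trinucleotides were at 2.02% ± 0.178 and 1.90% ± 0.174, CAG and CTG at 12.3% ± 0.865 and 11.3% ± 0.959, and CCG at 9.25% ± 0.757 and 8.62% ± 0.688. No group of trinucleotides differed beyond the spread between replicates, with exact permutation p of 0.4, 0.4, 0.2 and 0.5 in that order, and adjusted p over the 12 single trinucleotides from 0.6 to 0.7.

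The genome was then divided into 100-bp bins by pattern of methylation, without annotation. Bins with CHG or CHH methylation, the pattern of silenced transposable elements, are called TE-like (182483 bins). Bins with CG methylation alone, the pattern of gene bodies, are called gene-body-like (131561 bins). The CG level of TE-like bins was 81.9% ± 1.27 (SD, n = 3) after water and 82.8% ± 0.565 after JA, a difference of 0.852 points (SE 0.803) with overlapping groups and an exact permutation p of 0.4. Under lower class limits this difference was -0.0410. TE-like CHG was at 46.0% ± 0.907 and 45.2% ± 0.886 (exact permutation p = 0.4), and TE-like CHH at 12.3% ± 0.462 and 12.1% ± 0.483 (exact permutation p = 0.6). Gene-body-like CG was at 65.9% ± 0.559 and 66.4% ± 0.0947 (exact permutation p = 0.3).

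Deeply read repeats had a large part in these levels: 2808 CG cytosines with more than 100 reads per library, such as those of the 45S rRNA genes, held 10.3% of the nuclear CG reads. Without them, a choice made after seeing the data, CG methylation of TE-like bins was higher in all 3 JA libraries than in all 3 water libraries. The level was 85.0% ± 0.488 (SD, n = 3) after water and 86.7% ± 0.395 after JA, a difference of 1.68 points (SE 0.362, exact permutation p = 0.1, the smallest this design can give). The removed cytosines had CG levels of 48.4%, 48.2% and 56.995% in water replicates 1, 2 and 3, and 48.7% ± 1.37 after JA. On them, water replicate 3 stood apart. With the repeats kept and water replicate 3 left out, the TE-like CG difference was 1.59 points, close to 1.68. Without the repeats, water replicate 3 (85.5%) still lay below the lowest JA library (86.2%). CHG in the same bins was at 47.9% ± 0.624 and 47.3% ± 0.870 (exact permutation p = 0.5), and CHH at 12.9% ± 0.406 and 12.7% ± 0.505 (exact permutation p = 0.6). The gap between the CG and the CHG level of TE-like bins was itself 2.20 points wider after JA (SE 0.421, exact permutation p = 0.1), with no overlap between the groups.

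**Figure D2:**
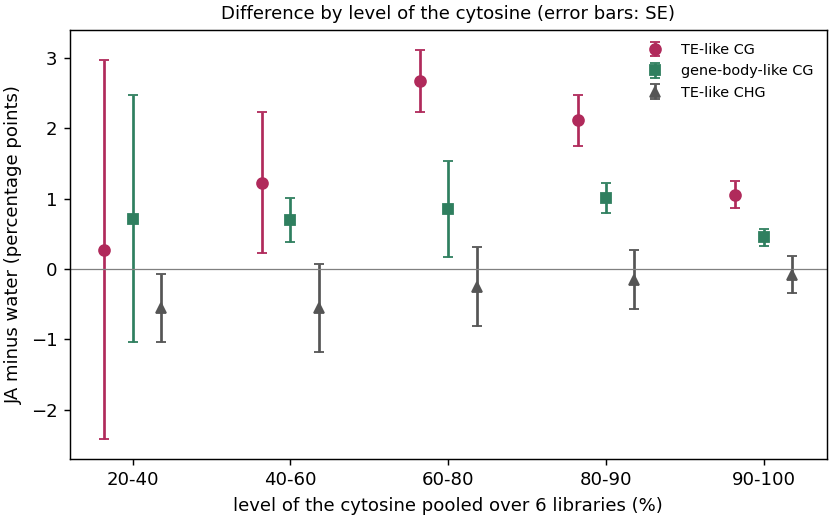
Difference in level, JA minus water in percentage points (vertical axis, error bars SE, n = 3 per group), of cytosines grouped by their level pooled over the 6 libraries (horizontal axis, percent), without deeply read repeats. At cytosines of 80% to 90%, TE-like CG had a difference of 2.12 points, gene-body-like CG one of 1.01 and TE-like CHG one of -0.147.

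**Figure D3:**
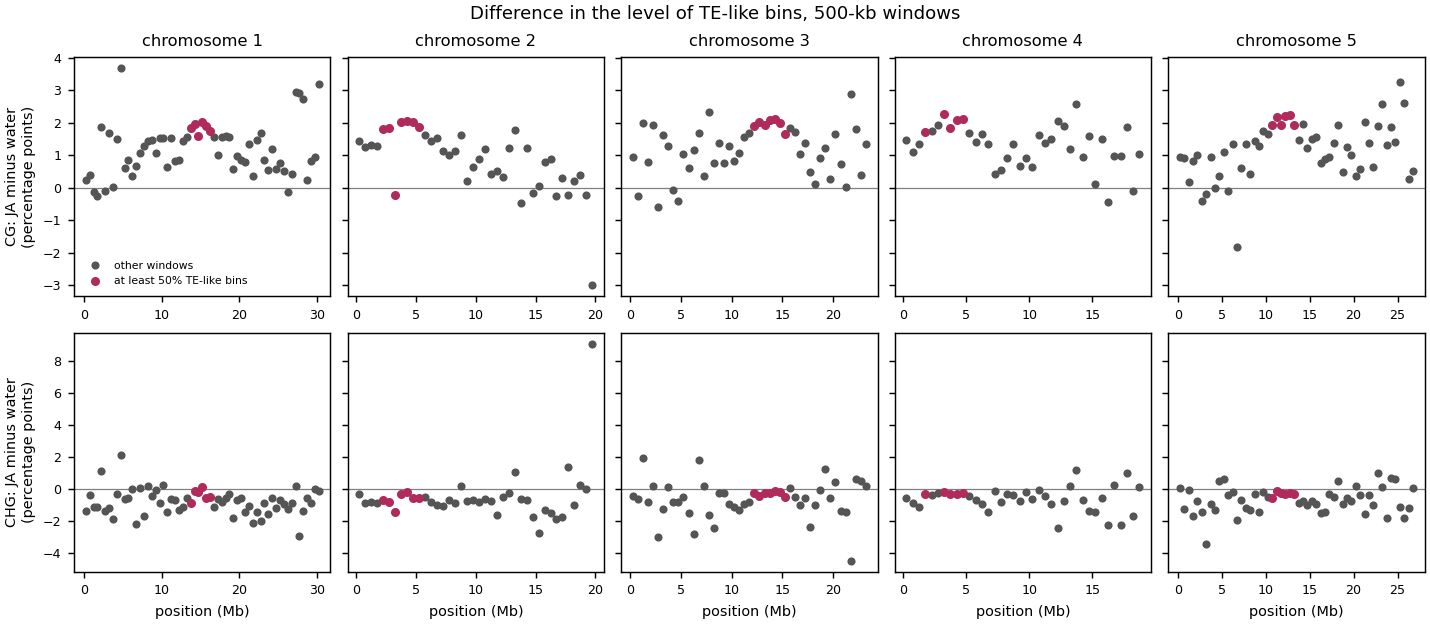
Difference in the level of TE-like bins, JA minus water in percentage points (vertical axis), in 500-kb windows along chromosomes 1 to 5 (horizontal axis, Mb), for CG (top) and CHG (bottom), with windows of at least 50% TE-like bins in magenta. CG was higher after JA in 218 of the 240 windows and CHG in 39.

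Few single 100-bp bins passed the test, while CG bins as a set were shifted. Over the 80515 tested CG bins the mean level was 76.2% ± 0.455 (SD, n = 3) after water and 77.6% ± 0.235 after JA, without overlap of the groups, and 62.1% of the bins were higher after JA. All JA libraries lay above all water libraries in 8.58% of the bins and below in 2.77%, where chance gives 5% each way on average. The bins share the same libraries and can shift together, so these shares are not a test. In CG, 2 of 80515 tested bins passed, and both were higher after JA. At AT3G06365, a non-coding RNA locus next to 45S rRNA genes (TAIR10 chromosome 3, 14203801 to 14203900), the CG level was 76.8% ± 0.0842 (SD, n = 3) after water and 79.8% ± 0.249 after JA (adjusted p = 0.00160, limma-squeezed quasi-binomial test). At AT2G00340, a non-coding RNA locus at the rDNA end of chromosome 2 (10101 to 10200), it was 83.7% ± 0.599 and 86.5% ± 0.315 (adjusted p = 0.000941). Between 10787 and 33675 reads per library lay on these bins, where the reads of many repeat copies pile up. The test called unchanged bins of more than 100 reads per cytosine too often on simulated data, in 26 of its 28 false calls in CG. The simulation gave all bins of a context the same spread beyond read sampling, whatever their depth. The 2 called bins varied little between libraries (SD 0.0842 to 0.599 points), and whether the false calls apply to them was not tested. With a dispersion prior that follows coverage, added after the false calls were seen, adjusted p was 0.831 and 0.811, and no CG bin passed. By edgeR and limma 0 were called too. At an unadjusted p under 0.05 there were 4939 CG bins. Without water replicate 3 the planned test called 4 CG bins, and without the filter on the pooled level it called 38 (32 higher and 6 lower after JA).

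In CHG, 0 of 54722 tested bins passed, and 2653 had an unadjusted p under 0.05. In CHH, 0 of 112927 passed, and 5320 had an unadjusted p under 0.05. edgeR and limma called 0 in both contexts. Without water replicate 1 or water replicate 2, the CHG test called 11 or 12 bins, and without water replicate 3 the CHH test called 1. Without the filter on the pooled level, 89 CHG bins (14 higher and 75 lower after JA) and 239 CHH bins (78 higher and 161 lower) were called. The lowest p in CHG belonged to bins in rRNA genes and their neighbours (AT2G01010, AT3G41768 and AT3G06365, with differences of -3.83, -5.29 and -3.21 points), to the pseudogene AT2G07677 (24.0% ± 5.37 after water, 14.4% ± 1.81 after JA) and to the pseudogene AT5G19097 (60.5% ± 5.28 and 78.0% ± 5.31). The bins at AT2G01010, AT3G41768 and AT3G06365 held 1939 to 15926 reads per library, and the groups overlapped in each. Of the 25 false CHG calls on simulated data, 19 were bins of more than 100 reads per cytosine. In CHH the bins with the lowest p lay between genes. A bin on chromosome 1 (18962001 to 18962100), 1105 bp from AT1G51172, had 32.3% ± 5.68 after water and 5.88% ± 4.14 after JA (adjusted p = 0.164). A bin near AT4G08691 had 26.9% ± 12.5 and 3.91% ± 0.278, one near AT5G02975 had 78.1% ± 1.33 and 60.3% ± 8.44, one near AT1G59171 had 21.7% ± 1.48 and 52.6% ± 13.6, and one near AT5G37442 had 28.7% ± 4.27 and 10.3% ± 4.28. None of these passed. At this depth, spread and number of libraries, of 50 simulated bins with a change of 20 points, the test recovered 38% in CG, 24% in CHG and 68% in CHH, and of those with 10 points 0%, 0% and 18%. The simulated changes raised low levels and lowered high ones. Recovery of a rise at high CG levels or a fall at low CHH levels was not simulated.

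No gene body passed the test. In CG, 0 of 12473 tested gene bodies were called, with 879 at an unadjusted p under 0.05, and edgeR and limma called 0. Without JA replicate 1 the test called 1. The mean CG level of these genes was 30.6% ± 0.398 (SD, n = 3) after water and 30.6% ± 0.229 after JA. The lowest p belonged to AT5G60710 (38.0% ± 0.773 after water, 45.0% ± 0.517 after JA, adjusted p = 0.304), AT5G11720 (9.37% ± 0.739 and 13.2% ± 0.639), the receptor kinase gene RLK, AT2G37710 (9.13% ± 0.821 and 14.5% ± 2.81), AT5G67220 (31.2% ± 1.88 and 22.8% ± 2.61) and AT3G58730 (46.7% ± 1.24 and 34.9% ± 2.83). Over all tested gene bodies, the groups did not overlap in 12.0%, where chance gives 10% on average.

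In CHG, 0 of 1280 gene bodies passed (67 at an unadjusted p under 0.05, 0 by edgeR and limma, and 6, of which 4 lower after JA, without the level filter). The lowest p were those of AT2G41650 (43.7% ± 3.32 after water, 34.3% ± 0.992 after JA), AT1G13470 (30.9% ± 2.25 and 40.1% ± 3.60), AT1G35610 (53.2% ± 2.02 and 40.4% ± 3.56), AT5G07410 (27.6% ± 1.85 and 18.9% ± 1.01) and AT2G07806 (12.3% ± 1.64 and 9.67% ± 0.756). In CHH, 0 of 770 passed (38 at an unadjusted p under 0.05, 0 by edgeR, 1 by limma). The lowest p were those of AT1G57775 (13.3% ± 6.79 and 3.80% ± 3.20), AT1G43720 (9.98% ± 1.01 and 7.59% ± 0.914), AT2G05540 (8.33% ± 1.48 and 14.5% ± 4.095), AT5G24990 (7.72% ± 1.05 and 12.2% ± 4.30) and AT5G42957 (22.8% ± 4.43 and 12.3% ± 7.21). A simulated change of 10 points was recovered in 48% of gene bodies in CG, 62% in CHG and 88% in CHH.

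Flanks of 1 kb on both sides of each protein-coding gene stood in for promoters, since the gene table gives no strand. In CG, 1 of 12471 tested flanks passed: the flank at the higher-coordinate side of AT2G01023, in the rDNA end of chromosome 2, with 79.7% ± 0.566 (SD, n = 3) after water and 82.1% ± 0.364 after JA (adjusted p = 0.00116). It held 49254 to 68477 reads per library, and with the prior that follows coverage its adjusted p was 0.933. Under that prior the flank of TPC1 (AT4G03560), the gene of a vacuolar cation channel whose gain-of-function alleles raise jasmonate synthesis, was called instead. It is named after its values were seen. Its CG level was 19.5% ± 4.60 after water and 39.2% ± 0.560 after JA, with adjusted p = 0.0629 in the planned test and 0.0357 under the added prior, on 169 to 369 reads per library. edgeR and limma called 0 CG flanks, and 747 had an unadjusted p under 0.05. Without water replicate 1 the planned test called 4 flanks, and without water replicate 2 or JA replicate 2 it called 2; without the level filter it called 21, 10 higher and 11 lower after JA.

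In CHG, 0 of 3903 flanks passed (179 at an unadjusted p under 0.05, 0 by edgeR and limma, and 16, of which 14 lower after JA, without the level filter). The lowest p were those of flanks of AT2G07739 (10.6% ± 2.16 after water, 4.40% ± 1.33 after JA), AT2G07795 (12.3% ± 3.02 and 5.25% ± 1.24), AT1G23915 (54.5% ± 0.610 and 46.0% ± 1.66), AT1G35660 (66.6% ± 2.48 and 58.7% ± 2.08) and AT2G07775 (16.6% ± 2.20 and 11.1% ± 3.33). AT2G07739, AT2G07795 and AT2G07775, like AT2G07806 and AT2G07677 above, lie in a part of chromosome 2 (3250001 to 3500000) that resembles mitochondrial DNA and was read, per CG cytosine, at 1.71 times the nuclear mean in both groups. In CHH, 0 of 3637 flanks passed (186 at an unadjusted p under 0.05, 0 by edgeR and limma). The lowest p were those of flanks of AT5G39890 (27.0% ± 0.727 and 38.8% ± 1.22), AT1G59171 (38.3% ± 2.29 and 61.0% ± 9.50), AT4G08691 (16.9% ± 6.75 and 4.39% ± 1.89), the cytochrome P450 gene CYP71A16 (9.03% ± 1.65 and 19.4% ± 7.13) and the glycine-rich protein gene GRP3S (13.2% ± 2.03 and 20.7% ± 4.07).

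The 8 gene lists fixed beforehand hold 162 genes of jasmonate, ethylene and salicylic acid signalling, defence, glucosinolates, DNA methylation and immune receptors. CG methylation of the gene body was under 5% in 84 of them, and 91 had at least 1 body or flank with enough methylation to test. Of their 173 tested features, 0 were called over all genes. When adjusted over the list alone, separately for each kind of feature and context, 3 were called; with all tested features of a list adjusted together, a choice made after seeing the data, 1 was. Of the 173, 16 had an unadjusted p under 0.05, and edgeR and limma called 0. After JA, 88 features were higher and 85 lower, before any test.

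For JA synthesis and signalling (14 of 34 genes tested), 0 of 27 features passed with all of them adjusted together. The lowest p was that of the body of LOX2, the chloroplast lipoxygenase of jasmonate synthesis, whose CHG level was 16.1% ± 1.80 (SD, n = 3) after water and 12.1% ± 1.85 after JA (adjusted p = 0.0102 over the list alone in that kind and context, where it was the 1 feature tested, 0.275 over the 27 and 0.841 over all genes). Its CG level was 52.8% ± 0.720 and 48.1% ± 2.25, lower in all 3 JA libraries than in any water library (adjusted p = 0.631). For jasmonate and ethylene defence outputs (10 of 19 genes tested) 0 features passed either way, and the lowest p was that of a flank of VSP1, a wound-induced storage protein gene (CG 87.4% ± 1.65 and 91.1% ± 2.90). For the glucosinolate pathway (5 of 27 genes tested) 0 passed, and SOT18, a sulfotransferase of glucosinolate synthesis, had 18.7% ± 3.80 and 16.0% ± 0.864 in CG. For salicylic acid defence (8 of 17) 0 passed, and NPR3, a salicylic acid receptor gene, had 12.9% ± 0.552 and 16.8% ± 2.64 in CG. For ethylene signalling (7 of 7) 0 passed, and CTR1, the kinase that represses ethylene responses, had 15.9% ± 2.41 and 19.5% ± 1.09 in CG.

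For DNA methylation and small RNA machinery (30 of 35 genes tested), 0 of 50 features passed and 4 had an unadjusted p under 0.05. The body of NRPD2, a subunit shared by RNA polymerases IV and V, had CG levels of 44.0% ± 1.10 (SD, n = 3) after water and 38.1% ± 2.68 after JA (adjusted p = 0.502). CMT2, the CHH methyltransferase, had 18.03% ± 0.831 and 20.6% ± 0.542 in the body and 19.7% ± 1.55 and 14.5% ± 2.70 in a flank. Among genes known to carry methylation marks (5 of 9 tested) 0 passed, and a flank of SDC, an F-box gene silenced by methylation, had 83.4% ± 4.04 and 75.9% ± 3.36 over 7 CG cytosines; its difference changed sign at a minimum of 1 read.

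For NLR immune receptors (12 of 14 genes tested), 8 of 26 features had an unadjusted p under 0.05, and 1 passed with all 26 adjusted together. The body of SNC1, a receptor gene of the RPP5 cluster, had CG levels of 30.2% ± 0.423 (SD, n = 3) after water and 24.8% ± 2.09 after JA (adjusted p = 0.0391 over the 26, 0.0135 over the 9 gene bodies tested in CG and 0.383 over all genes). A flank of RPP1, which recognises downy mildew, had CHH levels of 15.8% ± 3.42 and 24.4% ± 3.74 (adjusted p = 0.0463 over the 2 flanks of the list tested in CHH, 0.125 over the 26 and 0.882 over all genes). RPP4, in the same cluster as SNC1, had 42.2% ± 1.25 and 38.3% ± 0.972 in CHG of the body, and RPP5, of that cluster too, had 7.83% ± 0.863 and 10.4% ± 2.37, in the opposite direction, while flanks of RPM1 and RPS6 had 48.9% ± 2.50 and 56.1% ± 1.46, and 6.51% ± 0.705 and 14.1% ± 3.25, in CG.

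Transposable elements could not be tested one by one, since the gene table holds none, and the ATREP2 family was not analysed here. Pseudogene loci of the gene table were tested in their place, a choice made after seeing the data; 3178 of the 3555 tested (89.4%) lie mostly in TE-like bins. Their mean CG level was higher in all 3 JA libraries than in all 3 water libraries. The mean CG level over loci was 82.2% ± 0.410 (SD, n = 3) after water and 84.1% ± 0.368 after JA, and 83.7% of the loci were higher after JA. The test called 210 loci, 209 of them higher after JA. The rise at these 209 had a median of 3.39 points and ran from 1.40 to 12.7. They were picked by the test, and the median difference of all 3555 tested loci was 1.89 points. Called loci were also read more, with a median of 2179 reads per library beside 597 for all tested. Over all tested loci, the groups were apart with JA above in 25.6% and with JA below in 0.788%, where chance gives 5% each way on average. The loci share the same libraries and can shift together, so these shares are not a test. For the same reason the number of called loci adds little to the comparison of 3 libraries with 3, where no exact permutation p can fall below 0.1.

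The called loci with the lowest p were AT3G31945 (86.9% ± 1.04 after water, 89.8% ± 0.511 after JA, SD, n = 3), AT5G33252 (83.2% ± 0.933 and 87.4% ± 1.21), AT5G30207 (86.9% ± 0.701 and 90.9% ± 0.824), AT1G43883 (88.6% ± 1.18 and 91.4% ± 0.697) and AT4G06604 (86.7% ± 1.36 and 89.7% ± 0.353), each with adjusted p = 0.00160. The only locus called lower was AT2G07682, in the part of chromosome 2 that resembles mitochondrial DNA (42.5% ± 3.51 and 38.1% ± 3.32, adjusted p = 0.0144). edgeR called 152 loci, 136 of them among the 210; the prior that follows coverage called 130, with 122 shared; limma called 0. With the mean level of the tested loci as offset, 4 loci passed and all were lower, so the calls rest on a shift that most loci share. The count depended on single libraries: it was 109, 70 and 332 without water replicate 1, 2 and 3, and 146, 57 and 60 without JA replicate 1, 2 and 3.

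In CHG, 0 of 3440 pseudogene loci passed (170 at an unadjusted p under 0.05, 0 by edgeR, 1 by limma), and the mean level was 42.4% ± 0.392 (SD, n = 3) after water and 42.1% ± 0.666 after JA. The lowest p were those of AT1G37110 (54.4% ± 0.678 and 57.4% ± 1.21), AT1G36610 (55.6% ± 0.974 and 59.2% ± 0.963), AT1G35110 (48.9% ± 3.71 and 43.5% ± 3.67), AT4G10990 (60.1% ± 1.49 and 56.9% ± 0.277) and AT5G33252 (52.1% ± 1.16 and 54.7% ± 0.791). In CHH, 0 of 3088 passed (121 at an unadjusted p under 0.05, 0 by edgeR and limma), with mean levels of 11.2% ± 0.271 and 11.1% ± 0.345. The lowest p were those of AT3G43863 (7.15% ± 1.68 and 13.8% ± 2.95), AT5G33431 (10.4% ± 0.884 and 7.73% ± 0.506), AT2G16140 (13.1% ± 0.684 and 11.6% ± 0.322), AT4G10990 (23.2% ± 1.08 and 21.0% ± 0.793) and AT2G16832 (16.4% ± 1.69 and 12.3% ± 0.756).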

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

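Pseudogene loci, the settings named below as added, and for classes and trinucleotides the runs without single libraries, with the replicate block or with per-cytosine means were chosen after the data were seen, as were the coverage minimum and the chloroplast correction for classes. Of 1061 values of the 63 named features under alternatives, 948 kept direction and side of the threshold, 29 lost and 83 gained a call, and 1 changed direction: the flank of SDC (AT2G17690), at 2.13 with a coverage minimum of 1. The 29 lost calls fell on 9 features, the only ones of the 63 called in the main test. Each called feature thus lost its call in at least 1 setting, and the 948 are mostly values of features that stayed uncalled. The tests of transposable elements, their families and ATREP2 were not run, as the gene table holds no such elements. Where a count or direction differs below, the cause was not tested unless the setting's construction shows it.

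Global CG was -0.976 by reads and turned to 0.433 as a mean per cytosine, to 0.549 as such a mean at 4 reads (added) and to 0.122 with classes weighted by cytosines (added); without single libraries it ran from -1.67 to -0.121. TE-like CG was 0.852 and turned to -0.0410 under lower class limits, which take in more bins. As a mean per cytosine (added) it was 1.59, and without single libraries it ran from 0.483 to 1.59. Gene-body-like CG was 0.523, and 0.646 as a mean per cytosine (added, exact permutation p = 0.1). Without single libraries, gene-body-like CG ran from 0.248 to 0.806, global CHG from -1.38 to -0.476 and global CHH from -0.421 to -0.0781; TE-like CHG ran from -1.29 to -0.332 and TE-like CHH from -0.521 to -0.00324, while CAA and CTA ran from -0.887 to -0.172, other CHH from -0.214 to -0.0234, CAG and CTG from -1.49 to -0.524, and CCG from -0.976 to -0.224. As means per cytosine the differences outside CG kept their sign and were nearer 0: global CHG moved from -0.927 to -0.119 and global CHH from -0.249 to -0.0608, and (added) TE-like CHG from -0.824 to -0.585, CAA and CTA from -0.532 to -0.0965, other CHH from -0.121 to -0.0464, CAG and CTG from -1.01 to -0.126, and CCG from -0.626 to -0.0856, while TE-like CHH stayed near -0.275, at -0.274.

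CG bins numbered 2 as called. They were 0 by edgeR, by limma, with the prior by coverage (added), without collapsed repeats (added) and with a minimum difference, 5 with a library-wide offset, 1 and lower with an offset at the mean of the tested features (added), 38 without the level filter, 1 as 1000-bp bins (added), 1115 by Fisher's test, and 2 to 4 without single libraries. CHG bins, 0 as called, were 181 by Fisher's test, 1 with the library-wide offset, 89 without the level filter (75 lower) and 0 to 12 without single libraries. CHH bins, 0 as called, were 1156 by Fisher's test, 239 without the level filter (161 lower) and 0 to 1 without single libraries. Fisher's test takes no account of the spread between replicates.

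Gene bodies, 0 as called, were 1368 in CG, 37 in CHG and 88 in CHH by Fisher's test, 6 in CHG without the level filter, 1 in CHH by limma, and in CG 0 to 1 without single libraries. CG flanks, 1 as called, were 0 by edgeR, by limma, with the library-wide offset, with a minimum difference and without collapsed repeats (added), 306 by Fisher's test, 21 in both directions without the level filter, and 1 to 4 without single libraries. CHG flanks, 0 as called, were 39 by Fisher's test, 16 without the level filter and 1 with 500-bp flanks; CHH flanks, 0 as called, were 423 by Fisher's test. The gene lists, with 0 features called, had 14 by Fisher's test; the 3 called over the list alone, within a kind and context, were 1 with all features of a list adjusted together (added), which takes in more tests.

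Pseudogene loci in CG, 210 as called, were 0 by limma, 1234 by Fisher's test, 130 with the prior by coverage, 547 with the library-wide offset, 4 and all lower with an offset at the mean of the tested loci, 0 with a minimum difference, 45 at a coverage minimum of 8, where fewer reads remain, and 57 to 332 without single libraries. In CHG, 0 as called, they were 1 by limma and 36 by Fisher's test, and in CHH, 0 as called, 222 by Fisher's test.

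With the replicate number as a block, although the numbers showed no strong pairing, there were 1 CG bin, 24 CHG bins (all lower), 3 CG gene bodies, 5 CG flanks (2 higher, 3 lower) and 326 CG pseudogene loci. At this depth, spread and number of libraries a simulated change of 20 points was found in 38% of CG bins, 24% of CHG bins and 68% of CHH bins.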

Other observations

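All tests in this part were chosen after the results were seen.

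The higher CG level after JA was found in each class of window and of bin CHH level compared, though not evenly. By the pooled level of the TE-like CG cytosine, the groups overlapped at 20% to 40% (0.279 points, SE 2.70) and at 40% to 60% (1.23, SE 0.9995). At higher pooled levels they did not overlap. Without deeply read repeats, TE-like CG was higher after JA by 1.91 points (SE 0.428, n = 3) in 500-kb windows with at least 50% TE-like bins, which lie mainly around the centromeres, and by 1.34 points (SE 0.276) in the other windows. All 3 JA libraries lay above all 3 water libraries in 122 of 240 windows and below in 2, where chance gives 5% each way on average. In CHG this was 1 window above and 16 below, and in CHH 2 and 9. The windows share the same 6 libraries and can shift together, so such shares are not a test. By the CHH level of the bin, the CG difference was 1.63 points (SE 0.428) at 0% to 5%, 1.80 (SE 0.374) at 5% to 15%, 1.45 (SE 0.313) at 15% to 30% and 0.843 (SE 0.228) at 30% or more, each without overlap of the groups (exact permutation p = 0.1). No element lengths, small RNAs or mutants were examined, so the classes by CHH level were not assigned to silencing pathways.

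Gene-body-like bins took a smaller part in the gain. Without deeply read repeats, their CG cytosines of 80% to 90% pooled level were higher after JA by 1.01 points (SE 0.212, n = 3). Those of 90% to 100% were higher by 0.452 points (SE 0.119). The groups did not overlap in either (exact permutation p = 0.1), and they overlapped at lower pooled levels. The CG level of TE-like bins stood 18.6 points ± 0.201 (SD, n = 3) above that of gene-body-like bins after water and 19.7 ± 0.327 after JA, a difference of 1.12 points (SE 0.222, exact permutation p = 0.1, no overlap). The JA level of TE-like bins was 1.02 times the water level in CG (SE 0.00432) and 0.989 times in CHG (SE 0.0129).

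The higher CG level of TE-like bins and pseudogene loci was weighed against technical explanations. Loss of methylated calls by over-conversion in the water libraries would raise CHG cytosines of the same level alike, but at 80% to 90% the CHG difference was -0.147 (SE 0.421) beside 2.12 (SE 0.358) in CG. Poorer conversion in the JA libraries would raise the chloroplast level, which differed by -0.00176 (SE 0.0360). A difference in depth is argued against by CG cytosines read exactly 4 times, which differed by 1.44 points (SE 0.251). Open and untested remain the JA treatment, a difference in leaf age or cell types between the pools, and a library batch that the labels do not give.

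The global CG level was lower after JA by reads and higher by cytosines. TE-like bins held 22.9% ± 1.12 (SD, n = 3) of the nuclear CG reads after water and 21.5% ± 1.26 after JA (exact permutation p = 0.2). With each class weighted by its number of cytosines the difference rose from -0.976 to 0.122 points, which is consistent with a smaller share of reads on methylated sequence in the JA libraries as the source of the lower level by reads. Why that share varied between libraries was not tested.

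The part of chromosome 2 from 3250001 to 3500000, whose sequence resembles mitochondrial DNA, holds 5 of the 15 CHG bins, gene bodies and flanks with the lowest p, and the only pseudogene locus called lower in CG. Unmethylated CG reads on it, relative to nuclear depth, followed those on the mitochondrial genome across the 6 libraries (Pearson r = 0.984, exact permutation p = 0.00278; Spearman rho = 0.943, exact permutation p = 0.0167; 1 relation tested; r = 0.990 without the 2 libraries farthest from the median). A candidate explanation for the low levels there is mitochondrial DNA aligned to the nuclear copy, in amounts that differ between leaf samples. Its level was 36.9% ± 4.90 (SD, n = 3) in CG after water and 33.8% ± 3.66 after JA (exact permutation p = 0.5). In each of the 5 CHG features JA replicate 3 was lower than water replicates 1 and 2. It held fewer unmethylated mitochondrial CHG reads (2.42 per cytosine relative to the nuclear mean, beside 2.66 and 2.68). These features were picked for a low p between the groups and all were lower after JA, so their order cannot weigh against mitochondrial reads. Over the whole region the CHG level was 17.6% in JA replicate 3, beside 16.4% and 18.1% in water replicates 1 and 2. Methylated CHG reads per cytosine of the region, relative to the nuclear mean, were 0.316 ± 0.0286 (SD, n = 3) after water and 0.287 ± 0.0252 after JA (exact permutation p = 0.3). Unmethylated ones were 1.39 ± 0.114 and 1.43 ± 0.105 (exact permutation p = 0.7). The groups overlapped in both. Whether mitochondrial reads, a smaller share of reads on methylated sequence or a JA effect gave the lower levels stays open.

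The 6 libraries can be split in 10 ways into 3 and 3, too few to give a share under 0.05. The real split called 210 CG pseudogene loci and the highest other split 0 (1 split of 10 reached the real count); for CG bins these were 2 and 0 (1 split), and for CG flanks 1 and 1 (2 splits). The real split called 0 elsewhere, which all 10 splits reached: the highest other was 25 for CHG bins, 26 for CHH bins, 0, 1 and 6 for gene bodies in CG, CHG and CHH, 2 for flanks in CHG and in CHH, and 2 and 0 for pseudogene loci in CHG and CHH. The 25 CHG and 26 CHH bins came from 1 split, with water replicate 1, JA replicate 1 and JA replicate 3 on one side, and all lay lower on that side. These were also the 3 libraries with the lowest nuclear level, at 10.8%, 9.86% and 10.8% in CHG beside 11.6% to 12.4% in the others, and at 3.23%, 2.98% and 3.38% in CHH beside 3.60% to 3.83%. By their number such calls point to a structure of the libraries that does not follow the treatment, but the support is slight: the split was the highest of 9, and under the prior that follows coverage it called 0 and 2.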
